A study of Mus musculus with 8 samples.

How the data were processed

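Genomic DNA of E14Tg2a mouse embryonic stem cells was measured by whole-genome bisulfite sequencing in 8 libraries: 2 each of parental cells, METTL3 knockout cells, and knockout cells expressing wild-type or mutant METTL3. Per the labels, DNA was converted with the EZ DNA Methylation Gold kit and made into libraries after conversion with the Accel-NGS Methyl-Seq kit. The authors processed the reads with BSMAP 2.90 on build mm10. How reads were trimmed, whether duplicates were removed and how reads of repeats were placed is not given in the sources used here.

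The authors deposited 1 table per library, with a line for each CpG cytosine of each strand and columns as the aligner's methylation caller writes them. Per the file headers, the values are a count of methylated calls, a count of all calls, and the count of G and of G plus A calls on the opposite strand. The deposited tables also hold an expected or estimated count, the calls scaled by the opposite strand to allow for C-to-T variants. The deposited methylation ratio is a fraction, the methylated count over that expected count, with the bounds of its interval. Checked on the values, only cytosines of at least 5 calls are listed and counts stop at 65535. The strands were not merged and the replicates were not pooled by the authors.

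The 2 whole counts were used here, methylated calls and all calls, summed over the cytosines of a region and over both strands. A methylation level is methylated calls over all calls in percent, and a difference between groups is the difference of the mean of 2 library levels, in percentage points. Over all libraries 30030879 cytosines of 18764444 CpGs were listed, and 64576 cytosines were listed in all 8. Library totals ran from 45059299 to 123002247 calls, with a median of 6 calls per listed cytosine. Intervals and errors cover the spread between libraries or counting error only, since reads without molecular identifiers are not independent molecules. The labels do not say whether the replicates are separate cultures, so the p-values measure only the spread between these libraries. Cytosines that miss 5 calls are absent from the tables, so no statement of absence is made.

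Regions were autosomes as a whole, classes of CpG density, tiles of 10 kb on autosomes and X, gene ends and gene spans. Genes came from the RefSeq table given for GRCm38, which is mm10. The table has no strand, so a promoter could not be placed. In place of promoters, the end of each protein-coding gene with more CpGs within 1 kb on each side was used, counted on listed CpGs without regard to methylation. Of 21638 genes 74.4% had an end with at least 1.5 times the CpGs of the other. The choice can fail, and for Mettl3, Dnmt1 and Dnmt3a both ends were highly methylated. Gene spans run from the lower to the upper coordinate of a gene and were added after the files had been seen. The intracisternal A-particle (IAP) elements that the series title names were not analysed here, since neither a repeat annotation nor a genome sequence was used.

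Tiles needed at least 30 calls in each library, gene ends 10 and gene spans 30. Regions were tested with edgeR 4.0.16 in R 4.3.3, by a quasi-likelihood fit (glmQLFit with robust estimation) to methylated and unmethylated calls, with an intercept per library and group terms on the methylated column, all 8 libraries in a fit. The contrasts were knockout minus parental, rescue WT minus knockout, rescue Mut minus knockout and rescue WT minus rescue Mut. Each rescue against parental cells was computed with them. P-values were adjusted by Benjamini-Hochberg over the regions of a kind and contrast, and called at an adjusted p under 0.05. Limma 3.58.1 on logit2 methylation, with 0.5 added to each count, was the other tool, also with each library shifted to a common median. Lists were compared with all other genes by limma's camera with a preset correlation of 0.01 and with an estimated one, adjusted over 32 pairs of list and contrast. Levels of the whole genome were compared by an exact two-sided permutation test.

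On simulated data with the spread of these libraries, where 100 regions were changed by 30 points, edgeR called 41% of the tiles, 62% of the gene spans and 0% of the gene ends, and where they were changed by 15 points 2%, 0% and 0%. Of its calls 4.44% of tiles and 13.9% of gene spans were false, and of limma's 8% and 19.7%. The changed regions were few and of middle level, so these shares do not carry over to a difference shared by most of the genome. For recovery in rescued cells, unchanged groups were simulated against the same knockout libraries, since a shared group links contrasts.

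The genes named were chosen by a rule set before the data were examined: for promoters, the 10 with the largest rise and the 10 with the largest fall per contrast among called genes whose libraries of one group all lie on one side of the other group's, without predicted genes and without overlapping ones. For tiles it took 3 of each, and for the fixed lists up to 6 called members. The rule was carried over to gene spans, with at least 100 calls per library and 20 CpGs read in both groups added after the values had been seen. Mettl3, Dnmt1, Dnmt3a, Dnmt3b, Dnmt3l, Uhrf1, Setdb1 and Trim28 are always given. The 8 lists were fixed at the same time: imprinted genes, germline genes, pluripotency genes, lineage regulators, genes of the 2-cell stage, regulators of DNA methylation and heterochromatin, m6A machinery and markers of feeder fibroblasts. Symbols of 7 lists all matched, and 19 of 21 did for the 2-cell stage. A difference at shared CpGs is the mean difference over CpGs of at most 50 calls listed in both groups, calls of the libraries of a group joined.

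At Mettl3, calls per cytosine were counted in windows of 500 bases over the cytosines listed in any library and divided by the mean of the autosomes in the same library. A window was in excess when the mean of the rescue libraries was at least 4 times that of the others, taken as at least 1, every rescue library lay above every other and at least 10 cytosines were listed.

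Alternatives set before the data were examined were other minimum calls, a limit of 50 calls per cytosine, the mean over cytosines, the median over chromosomes, limma, the common median, thinning of calls to the shallowest library, a replicate block, a difference of at least 10 points, tiles of 100 kb, gene ends of 500 bases, an estimated correlation and leaving out each library. Added after seeing the data were shared cytosines, a correction for the mitochondrial level, leaving out cytosines with A on the opposite strand, thinning of the genome level, the other gene end, ends with a clear CpG-denser side, and gene spans for each result. Tables were read and summed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.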

Results

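Whole-genome bisulfite sequencing measured CpG methylation in E14Tg2a cells, a mouse embryonic stem cell line, grown with LIF, serum and inhibitors of MEK and GSK3. The 8 libraries form 4 groups of 2: parental cells, METTL3 knockout cells, knockout cells with wild-type METTL3 put back (rescue WT) and knockout cells with a mutant METTL3 put back (rescue Mut). METTL3 is the catalytic subunit of the complex that places m6A on RNA, and which residue the mutant changes is not given in the sources used here. The parental libraries listed 5758292 and 4727183 cytosines with 53765997 and 45059299 calls. The knockout libraries listed 4639234 and 4845758 with 45162283 and 46396201 calls, and the rescue WT libraries 5655542 and 6006279 with 53774094 and 56856602 calls. The rescue Mut libraries were deeper, at 14308047 and 11957564 cytosines and 123002247 and 102437483 calls. The median listed cytosine held 6 calls in every library, so the values below are sums over many cytosines. The mitochondrial genome, the background of unconverted or miscalled cytosines, read 0.575% to 0.843% methylated in 7 libraries and 2.53% in knockout replicate 2.

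The Mettl3 locus was compared first, since it shows what bisulfite data can of the genotypes. Over the Mettl3 gene (mm10 chromosome 14, 52294841 to 52308741), calls per cytosine relative to the autosomal mean of each library were 1.16 and 0.9947 in parental cells and 0.681 and 0.694 in knockout cells. They were 4.42 and 4.83 in rescue WT cells, and 2.43 and 2.28 in rescue Mut cells. The excess was largest in 3 windows of 500 bases between 52297501 and 52300500, with relative coverage of 12.3 ± 1.15 (SD, n = 2) in rescue WT, 4.72 ± 0.121 in rescue Mut, 1.89 ± 0.643 in parental and 0.250 ± 0.111 in knockout cells. These windows were picked because every rescue library lay above every other one there. Before division by the autosomal mean they held 16.4 calls per cytosine in rescue WT and 14.6 in rescue Mut cells. Cytosines of fewer than 5 calls are not listed, which lowers the autosomal mean more in shallower libraries. The relative values thus do not compare the rescue lines in copies of Mettl3. In the other 26 windows of the gene the relative coverage was 2.10 ± 0.0308 in rescue WT and 1.58 ± 0.102 in rescue Mut cells. It was 0.838 ± 0.373 in parental and 0.831 ± 0.0733 in knockout cells, again with every rescue library above every other. Of 947587 windows tested over the genome, 8 met the same rule, of which 3 lay in Mettl3, and 21 met the opposite rule. The rule for picking windows was set after the values at this locus were seen.

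**Figure D1:**
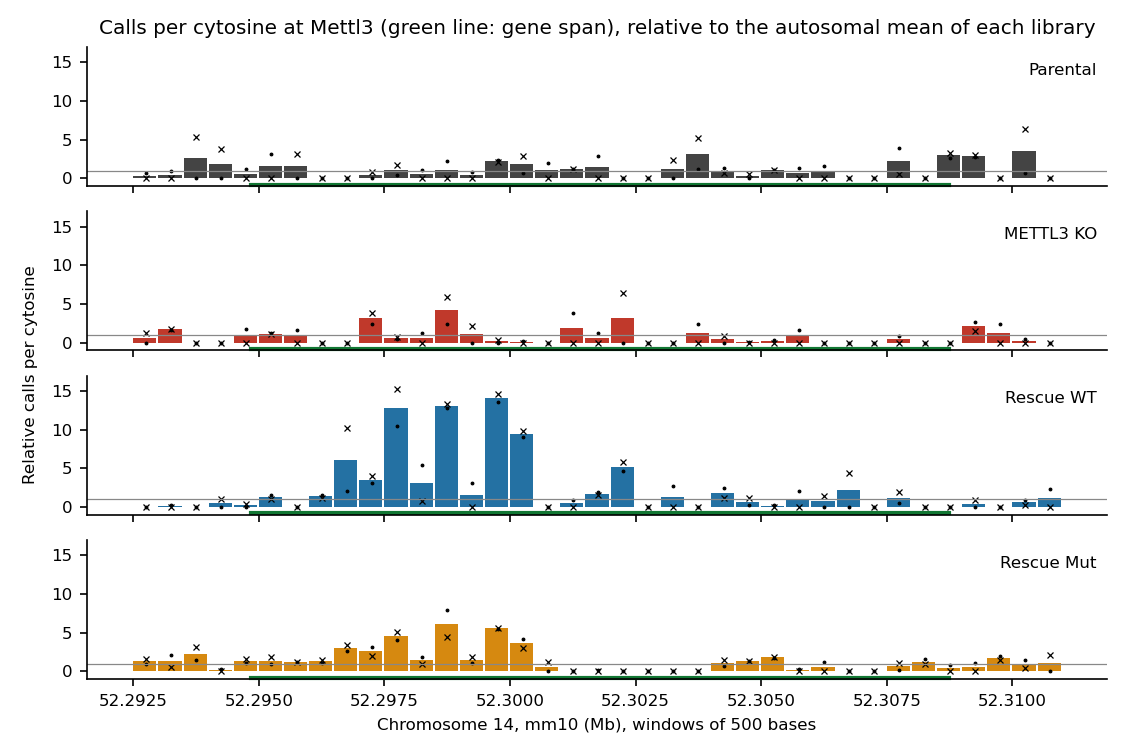
Calls per cytosine in windows of 500 bases over Mettl3 on chromosome 14 (horizontal axis, position in Mb), relative to the autosomal mean of each library (vertical axis), with bars for the mean of 2 libraries and marks for each library. Rescue WT reaches 12.3 and rescue Mut 4.72 over the 3 windows in excess, against 0.250 in the knockout. These sizes do not compare the rescue lines, whose libraries differ in depth.

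The series asks how DNA methylation differs between parental, METTL3 knockout and rescued cells, and the genome as a whole differed. Over all listed autosomal cytosines the methylation level was 63.2% ± 0.278 (SD, n = 2) in parental cells, 54.3% ± 0.290 in knockout cells, 64.0% ± 0.0574 in rescue WT cells and 46.8% ± 0.0304 in rescue Mut cells. Knockout cells were thus 8.94 percentage points below parental cells, rescue WT cells 9.73 points above the knockout and 0.790 points above parental cells, and rescue Mut cells 7.43 points below the knockout. The difference between the rescue lines was 17.2 points. Each of these differences exceeded the range of the libraries within a group, and knockout and rescue Mut cells lay below parental cells on all 19 autosomes.

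Cytosines of more than 50 calls, mostly in a few regions where reads pile up, held 17.3% to 31.5% of the calls, so the level was also taken without them. At cytosines of at most 50 calls in every library, the knockout lay 12.3 points below parental cells, rescue WT 13.1 points above the knockout and rescue Mut 4.01 points below it. Leaving out the cytosines above 50 calls moved these differences by similar amounts, and the knockout is part of each. The knockout read 54.3% with those cytosines and 47.1% without them. At 3449599 CpGs read in both groups, knockout cells were 11.8 points below parental cells, and at 6041271 CpGs read in both, rescue Mut cells were 4.05 points below the knockout. With 2 libraries against 2, the smallest p an exact two-sided permutation test can give is 0.333, so no genome-wide difference could pass it.

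Between knockout and parental cells regions of few CpGs differed most, at cytosines of at most 50 calls. With fewer than 5 CpGs within 250 bases on each side, the level was 61.5% ± 0.00863 (SD, n = 2) in parental and 45.9% ± 0.823 in knockout cells. With 5 to 9 CpGs it was 64.7% ± 0.0144 and 52.2% ± 0.655, and with 10 to 19 CpGs 58.1% ± 0.0881 and 50.7% ± 0.735. In CpG-dense sequence, with 20 or more CpGs, it was 17.9% ± 0.0982 and 17.9% ± 2.02, a difference smaller than the spread between the knockout libraries. Rescue WT cells read 63.4% ± 0.00720 in the sparsest class and rescue Mut cells 43.4% ± 0.0522. Rescue Mut minus knockout did not follow this order, at -2.52, -4.19, -4.84 and -3.72 points from the sparsest class to the densest. Gene spans and the sequence outside them differed alike, the knockout lying 11.9 points below parental cells inside protein-coding gene spans and 12.6 points below outside. The X chromosome lay 11.99 points below parental cells.

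**Figure D2:**
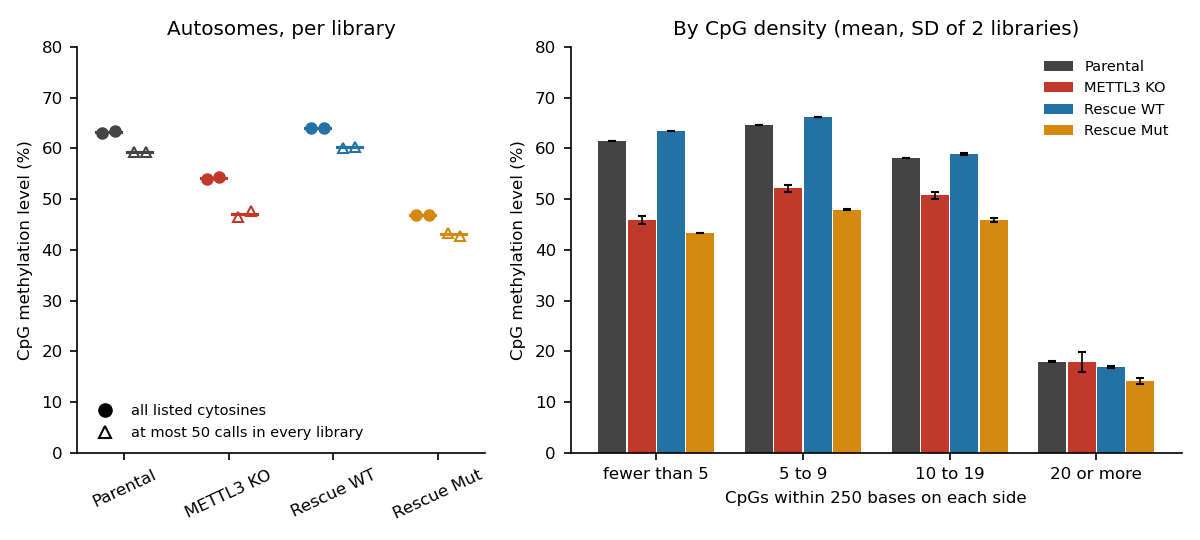
CpG methylation level in percent (vertical axes) per library for the 4 groups (left; circles, all listed autosomal cytosines; triangles, cytosines of at most 50 calls in every library; lines, means) and as the mean with the SD of 2 libraries by CpG density (right; CpGs within 250 bases on each side). Knockout and rescue Mut libraries lie below parental and rescue WT libraries in every class but the densest, where parental and knockout cells both read 17.9%.

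Methylation was next tested over 17706 protein-coding gene spans, from one annotated end of a gene to the other, a unit added after the files had been seen. In knockout cells, methylation fell over 5312 gene spans and rose over 78, and the median difference from parental cells over all spans was -11.0 points. The gene with the deepest fall among those named was Grsf1, an RNA-binding protein of mitochondrial RNA granules (chromosome 5, 88659233 to 88676171), which went from 63.7% ± 4.87 (SD, n = 2) to 15.9% ± 6.35 (edgeR adjusted p = 0.000606). Bok, a relative of Bcl-family apoptosis regulators, went from 67.0% ± 5.64 to 23.5% ± 17.1, Lox, which cross-links collagen, from 61.5% ± 13.5 to 21.3% ± 1.03, and Hif1a, the oxygen-regulated transcription factor, from 62.0% ± 6.08 to 22.8% ± 9.01. Unc50, Ccnh (cyclin H), Sv2a (a synaptic vesicle protein), Ddx51, Slc35g1 and Arrdc1 fell by 40.9 to 37.2 points. At the CpGs read in both groups the differences were smaller, -24.0 points for Grsf1, -19.3 for Lox and -9.72 for Hif1a, at 32, 28 and 36 shared CpGs, -14.2 for Bok and -22.4 to -8.49 for the other 6.

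Of the genes that rose, Prpf38b, a splicing factor (chromosome 3, 108902805 to 108911729), held its direction at shared CpGs, with 57.5% ± 10.99 (SD, n = 2) in knockout against 22.3% ± 13.97 in parental cells and 29.7 points at 28 shared CpGs. Paqr9, Slc30a2, Igfbp4 and Apba3 also rose, and they stood 6.95, 5.41, 0.692 and 10.6 points higher at shared CpGs. Ppif, Cxcl14, Rac3, Rab3a and Carnmt1 rose over the span but read -1.64, -2.11, -0.416, -2.91 and -5.04 points at shared CpGs, where the rise over the span was not seen. Of the spans that rose, 54 held at least 20 shared CpGs, and 40 of these were higher there too. Of the spans that fell, 5053 held as many and 5026 were lower there too, by a median of -13.5 points.

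EdgeR called 30.4% of all spans in this contrast, and the counts in the fixed gene lists are to be read against that share. By camera none of the lists in this paragraph was called over spans. Of 29 measured germline genes, 9 fell in knockout cells and 0 rose by edgeR (10 and 0 adjusted over the list alone). Among them were Mael, of the piRNA pathway, from 67.6% ± 2.35 (SD, n = 2) to 45.6% ± 3.25, Stk31 from 72.3% ± 1.01 to 53.6% ± 2.05 and the meiotic cohesin subunit Smc1b from 56.6% ± 4.70 to 41.8% ± 0.495. Of 26 imprinted genes 9 fell, led by Peg13, Snrpn, Sgce, Usp29 and Igf2r, and 1 rose, Nnat, from 10.5% ± 10.9 to 44.0% ± 8.20 (the same counts adjusted over the list alone). Of 19 genes of the m6A machinery 6 fell and 0 rose, also adjusted over the list alone. They were Zc3h13 and Virma, subunits of the m6A writer complex, the reader Ythdf2, the eraser Fto, Mettl16 and Igf2bp3. Ythdf2 went from 39.6% ± 3.71 to 20.1% ± 7.13, yet read 1.65 points higher at its 50 shared CpGs. Mettl16 fell by 10.6 points over the span but read only -1.12 points at its 185 shared CpGs. Zc3h13, Virma, Fto and Igf2bp3 read -19.2 to -7.05 points at theirs. Of 26 regulators of DNA methylation and heterochromatin 4 fell (3 adjusted over the list alone), the methyltransferase genes Dnmt3b, from 65.8% ± 2.44 to 46.4% ± 9.56, and Dnmt3a, with Ehmt1 and Tet3.

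Pluripotency genes and lineage regulators stood apart from other genes in that they differed less. Of 18 pluripotency genes 1 fell, Esrrb, from 44.1% ± 0.257 (SD, n = 2) to 37.4% ± 2.29, and of 25 lineage regulators 1 fell, the heart transcription factor Tbx5 (0 in each list adjusted over the list alone). The median differences were 1.34 and -1.92 points, and the mean differences 0.987 and -1.44 points, against -11.0 points over all spans. Limma's camera, which compares a list with all other genes, placed both higher than the rest (adjusted p = 1.61e-06 and 8.6e-05 over 32 list and contrast pairs). With an estimated correlation the calls were lost, at adjusted p = 0.0625 for each. Both lists held low levels to begin with, a median gene at 11.3% and at 16.3% in parental cells. Of 5 genes of the 2-cell stage 1 fell, Sp110, and of 11 feeder fibroblast markers 1 fell, Fn1 (also 1 in each adjusted over the list alone), and the median marker was 11.5 points lower, near the -11.0 points over all spans.

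These calls came from edgeR. Limma called 3596 of the spans, and once each library was shifted to a common median it called 0, with 2164 at an unadjusted p under 0.05 against 885.3 expected by chance. Without knockout replicate 1 edgeR called 3279.

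**Figure D3:**
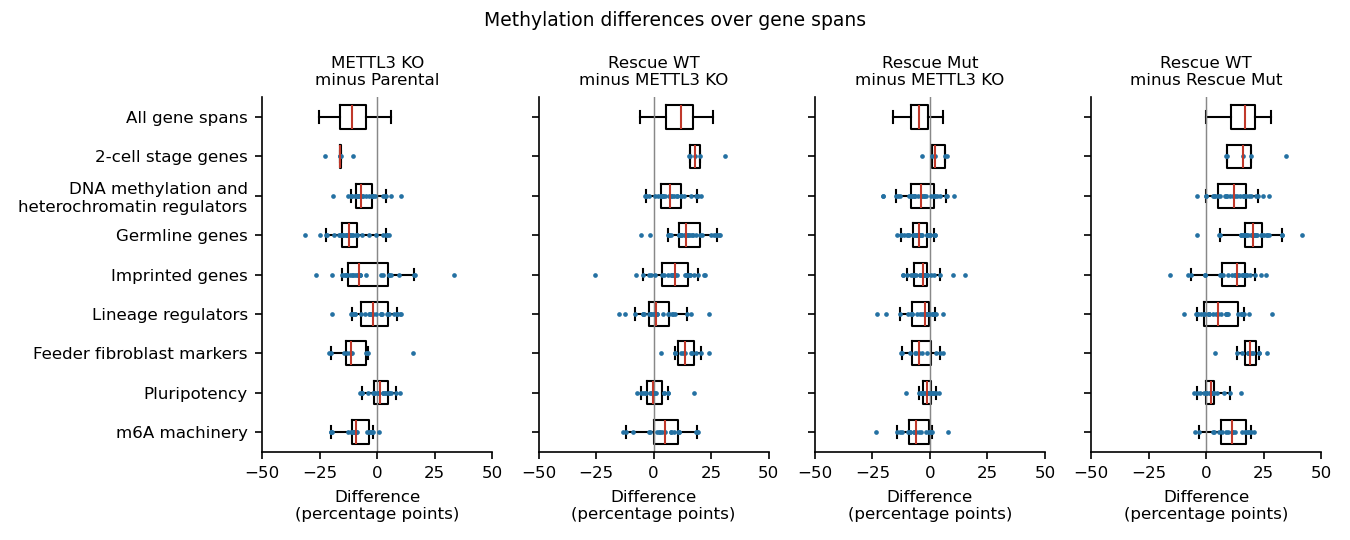
Difference in methylation level over gene spans in percentage points (horizontal axes) for 4 comparisons, for all spans and for 8 fixed gene lists, with boxes from the first to the third quartile, red lines at the median and points for single genes. Knockout minus parental has a median of -11.0 points over all spans and 1.34 points over the pluripotency genes.

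Over the genome in windows of 10 kb, the knockout showed the same one-sided difference. Of 189826 tiles with at least 30 calls in every library, 5962 fell and 72 rose in knockout cells, with a median difference of -13.1 points over all tiles. The deepest fall was at chromosome 5, 50630001 to 50640000, from 82.4% to 7.55%, where no protein-coding gene lies. This tile held only 35 calls in its shallowest library, and read -63.7 points at only 4 shared CpGs. The largest rise was in Gpa33, which encodes an intestinal cell surface antigen (chromosome 1, 166130001 to 166140000), from 11.7% to 64.1%, and this tile fell again to 12.5% in rescue WT cells. At its 17 shared CpGs the Gpa33 tile read 34.7 points higher in the knockout than in parental cells. Defb41, a beta-defensin, also overlapped a tile that rose, which held only 34 calls in its shallowest library and 5 shared CpGs. The tile count fell steeply when any parental, knockout or rescue Mut library was left out, although rescue Mut is outside this contrast. It was 7 and 6 without parental replicates 1 and 2, 14 and 12 without knockout replicates 1 and 2, and 20 without either rescue Mut replicate, against 6034 with all 8 libraries.

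The rescue WT line asks whether wild-type METTL3 restores methylation in knockout cells, and methylation rose over most of the genome. It rose over 6087 gene spans and fell over 71 relative to the knockout, with a median difference of 11.7 points, and it rose in 20629 tiles and fell in 154. Tbl3, which functions in ribosome biogenesis (chromosome 17, 24700653 to 24707653), went from 21.9% ± 13.1 (SD, n = 2) to 67.9% ± 3.77, Brox from 28.0% ± 3.21 to 71.8% ± 1.87, and Eif2b2, a subunit of a translation initiation factor, from 30.2% ± 2.31 to 72.6% ± 1.05. Slc35g1 and Arrdc1, which fell in the knockout, rose by 39.6 and 38.2 points. Zfp956, Maip1, AB010352, Trim39 and Ccdc97 rose by 39.8 to 37.6 points. At shared CpGs the differences were smaller, 15.9 points for Tbl3, 26.1 for Brox, 21.5 for Eif2b2, 28.7 for Slc35g1, 19.4 for Arrdc1, 8.38 for Zfp956, 20.2 for Maip1, 20.9 for AB010352, 5.88 for Trim39 and 18.9 for Ccdc97.

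Genes that fell in rescue WT cells included Zfp386, a zinc finger gene, from 60.3% ± 3.74 (SD, n = 2) to 32.1% ± 2.89, and Phox2a, a homeodomain factor of autonomic neurons, from 27.2% ± 4.25 to 7.89% ± 1.64. At shared CpGs these read -11.5 and -13.7 points. Zfp239, Acsbg3 and S100a7l2 also fell and read -6.07, -11.5 and -19.1 points there. Nfyb, Ing2, Gjb6, Zfp335 and Garem2 fell over the span but read 13.2, 2.91, 6.87, 0.0198 and 4.66 points higher at shared CpGs.

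Of all spans, 34.8% were called by edgeR between rescue WT and knockout cells, the share to set the list counts against. Of 29 germline genes 13 rose in rescue WT cells and 0 fell by edgeR (16 and 0 adjusted over the list alone). Ddx4, the germ cell RNA helicase, went from 47.9% ± 7.21 (SD, n = 2) to 75.0% ± 3.999, Brdt from 46.6% ± 10.3 to 71.7% ± 6.24 and Syce1 from 52.7% ± 4.55 to 80.2% ± 5.86. Of 26 imprinted genes 11 rose and 0 fell (12 and 1 adjusted over the list alone), including the neighbours Igf2r and Airn, which rose by 22.2 and 21.7 points, and Snrpn, Kcnq1ot1, Usp29 and Cdh15. Of 26 methylation and heterochromatin regulators 7 rose (7 adjusted over the list alone). Among these were Uhrf1, the partner of the maintenance methyltransferase, from 28.3% ± 5.16 to 49.1% ± 4.08, the H3K9 methyltransferase genes Setdb1 and Ehmt1, and Atrx, Morc3 and Dnmt3a. Of 19 m6A machinery genes 6 rose (6 adjusted over the list alone): Mettl16, Mettl3, Virma, Fto, Igf2bp1 and Igf2bp3. The Mettl3 span itself, which carries the excess calls, went from 38.1% ± 12.4 to 56.8% ± 2.49. Of 5 genes of the 2-cell stage 3 rose, Tmem92, Arg2 and Sp110 (3 adjusted over the list alone). Of 11 fibroblast markers 6 rose (6 adjusted over the list alone), among them Col3a1, Vim and Twist2. Vim rose by 20.7 points over the span but read -1.97 points at its 23 shared CpGs. Col3a1 and Twist2 read 19.7 and 10.99 points higher at theirs. None of the pluripotency genes or lineage regulators was called by edgeR, of which 18 and 25 were measured, and both lists lay lower than other genes by camera (adjusted p = 5.35e-06 and 1.82e-05; adjusted p = 0.0625 for each with an estimated correlation). Their median differences were -0.102 and 1.13 points, and their means 0.738 and 2.06 points, so the pluripotency median and mean differ in sign.

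Limma called 4918 of the spans and 15080 of the tiles, and after the shift to a common median 0 spans and 1 tile, with 2190 spans and 20412 tiles at an unadjusted p under 0.05. EdgeR called 3992 spans without knockout replicate 1, and its tile count was 13 and 6144 without knockout replicates 1 and 2, 11 and 10 without rescue WT replicates 1 and 2 and 16 and 17 without rescue Mut replicates 1 and 2.

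The rescue Mut line asks whether the mutant METTL3 does the same, and methylation did not rise. Relative to the knockout 33 gene spans fell and 1 rose, with a median difference of -4.59 points over all spans, and 13 tiles fell and 0 rose by edgeR. At an unadjusted p under 0.05, 10166 tiles were lower and 1412 higher, against 9491.3 expected by chance in all. The called genes were long and deeply read, and the falls were small. Itsn1, an endocytic scaffold (chromosome 16, 91729310 to 91920591), went from 54.3% ± 2.004 (SD, n = 2) to 43.8% ± 0.393, and Pcdhga3, a clustered protocadherin, from 34.5% ± 0.734 to 24.9% ± 0.857. Cox10, of haem A synthesis, Glis3, the polarity gene Pard3, Vps13d, Ptprg, Arl15 and Wwox fell by 9.64 to 7.28 points. Fto, the m6A demethylase, went from 57.0% ± 1.22 to 48.5% ± 0.623 and was the 1 list member called, of the 19 m6A machinery genes (also 1 adjusted over the list alone). Myo3a rose, from 19.2% ± 3.66 to 31.2% ± 0.564, but read 1.79 points at its 402 shared CpGs.

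Among the tiles, the deepest fall in rescue Mut cells overlapped Dda1 and Ano8 (chromosome 8, 71470001 to 71480000), from 64.2% to 16.5%. At its 45 shared CpGs this tile read -23.4 points. In the other 7 lists 0 spans were called by edgeR, and limma called 0 of all spans and 0 of all tiles. At an unadjusted p under 0.05 edgeR placed 2484 spans lower and 75 higher, against 885.3 expected by chance in all. Adjusted over the list alone, 1 of the methylation regulators also fell. Against 34 spans with all libraries, edgeR called 21 and 13 without knockout replicates 1 and 2, and 5 and 2 without rescue Mut replicates 1 and 2. After the shift to a common median limma called 0, with 814 at an unadjusted p under 0.05.

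Set against each other, the rescue lines differed over much of the genome. Methylation was higher in rescue WT than in rescue Mut cells over 9734 gene spans and lower over 31, with a median difference of 16.8 points, and higher in 63565 tiles and lower in 63. Ube2q1, a ubiquitin-conjugating enzyme gene (chromosome 3, 89773609 to 89783997), read 76.2% ± 1.29 (SD, n = 2) against 25.8% ± 4.60, Slc35g1 66.7% ± 0.811 against 18.1% ± 3.15, and Nop9 67.6% ± 8.02 against 20.2% ± 5.31. Lin7c, Cops8, Eif2b2, the tubulin gene Tuba1a, Trmt6 and Zfp619 were higher by 45.7 to 41.5 points. At shared CpGs these genes were higher by 15.4 points (Tuba1a) to 36.5 points (Ube2q1). Lower in rescue WT cells were Tcl1, a coactivator of AKT, at 32.1% ± 0.625 against 53.7% ± 3.17, Spry4, an antagonist of FGF signalling, at 15.0% ± 1.55 against 28.2% ± 0.936, and Glo1, Islr2, the homeobox gene Dlx1 and Jade1, by 9.27 to 5.91 points. Abhd17a and LOC102637806 were lower by 13.0 and 11.6 points and read -3.89 and -7.26 points at shared CpGs. Fcgr3 was lower over the span and read 0.188 points higher at shared CpGs. Among tiles, Trim2, Slc29a3 and Dusp27 overlapped those that were lowest in rescue WT cells, by 33.2, 28.9 and 26.9 points. At shared CpGs these tiles read -22.8, -33.5 and -17.4 points.

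Between the rescue lines edgeR called 55.2% of all spans, the share to set the list counts against. Of 29 germline genes 19 were higher in rescue WT than in rescue Mut cells (20 adjusted over the list alone). The furthest apart were Syce1, at 80.2% ± 5.86 (SD, n = 2) against 38.5% ± 0.885, Ddx4, Nanos3, Rpl10l, Sycp1 and Brdt. Of 26 imprinted genes 13 were higher (13 adjusted over the list alone), with Airn, Igf2r, Zdbf2 and Impact at the head. Of 26 methylation and heterochromatin regulators 12 were higher (11 adjusted over the list alone), with Atrx at 63.7% ± 5.49 against 36.6% ± 0.204 and Ehmt1 at 70.7% ± 0.303 against 45.9% ± 3.02. Of 19 m6A machinery genes 10 were higher (10 adjusted over the list alone), Fto at 68.1% ± 1.22 against 48.5% ± 0.623. Of 11 fibroblast markers 7 were higher (8 adjusted over the list alone), and of 5 genes of the 2-cell stage 3 (3 adjusted over the list alone). Of 25 lineage regulators 5 were higher, Elf5, Nes, Gata4, Pax6 and Tbx5 (2 adjusted over the list alone). Of 18 pluripotency genes Klf4 was higher, at 10.7% ± 9.31 against 3.19% ± 0.928, and Klf2 lower, at 0.512% ± 0.385 against 3.09% ± 2.07 (0 adjusted over the list alone). By camera the pluripotency genes and lineage regulators again differed less than other genes (adjusted p = 4.03e-09 and 6.4e-08; adjusted p = 0.0625 for each with an estimated correlation).

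Limma called 9129 of these spans and 31679 of the tiles, and after the shift to a common median 0 and 1, with 1411 and 8942 at an unadjusted p under 0.05. EdgeR called 5596 and 5129 spans without rescue Mut replicates 1 and 2, and 16250, 15987, 18 and 14 tiles without rescue WT replicates 1 and 2 and rescue Mut replicates 1 and 2.

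Recovery was then followed over the regions that differed in the knockout. Of 5390 gene spans called in the knockout, 4245 (78.8%) were called in the opposite direction in rescue WT cells, and 10 (0.186%) in rescue Mut cells, where 21 were called in the same direction. In the spans that fell in the knockout, by a median of 15.9 points, the median difference from parental cells was -0.155 points in rescue WT and -19.2 points in rescue Mut cells. In the tiles that fell, by a median of 34.5 points, it was -7.34 points in rescue WT and -27.6 points in rescue Mut cells. These medians show no recovery by themselves, since picking regions for a low knockout and a high parental level draws the median of any other group towards a place between the 2. Over all tiles the median difference was 1.34 points for rescue WT minus parental and -3.88 points for rescue Mut minus knockout cells. Rescue WT cells differed from parental cells over 2 of the 5390 spans and rescue Mut cells over 5031. Over all 17706 spans edgeR called 2 and 9150 (51.7%) in these comparisons. The parental libraries that helped pick the 5390 spans enter these calls too, and the rescue Mut libraries are deeper. These counts thus show no recovery by themselves either. Of 6034 tiles called in the knockout, 3279 (54.3%) were called the opposite way in rescue WT cells and 1 in rescue Mut cells.

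The knockout libraries enter both the knockout calls and the calls of each rescue against the knockout, so chance alone links them. Unlinked calls would give 1826 spans (33.9%) and 648 tiles (10.7%) in rescue WT cells. Over all spans the covariance of the knockout difference with the rescue WT difference was -59.1, against -27.9 for simulated unchanged groups set against the same libraries, and with the rescue Mut difference -33.4 against -27.5. The correlations over spans were -0.622 against -0.510 with rescue WT and -0.511 against -0.513 with rescue Mut. Over tiles they were -0.633 against -0.507 and -0.634 against -0.525, and the covariances -84.6 against -44.6 and -66.2 against -44.6, so the correlations over tiles did not tell the rescue lines apart. The share of spans was 60.9% and 59.5% without rescue WT replicates 1 and 2, and the share of tiles 0.157% and 0.141% without them and 100.0% and 100.0%, 85.7% and 91.7% without parental replicates 1 and 2 and knockout replicates 1 and 2, where few tiles were called at all.

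The ends of genes were taken in place of promoters. Around the CpG-denser end of protein-coding genes the level was 16.3% ± 0.124 (SD, n = 2) in parental, 13.6% ± 1.36 in knockout, 15.2% ± 0.255 in rescue WT and 10.5% ± 0.367 in rescue Mut cells. The rescue Mut level lay 5.83 points below parental and 4.75 points below rescue WT cells, beyond the range of the libraries within a group. Of 13576 gene ends tested, edgeR and limma each called 0 in all 4 contrasts. By edgeR 951 had an unadjusted p under 0.05 for knockout against parental cells. It was 923 and 352 for rescue WT and rescue Mut against the knockout, and 660 between the rescue lines. Evenly spread p-values would give 678.8. In the simulated data 2.28% of unchanged gene ends had such a p by edgeR, fewer than evenly spread p-values give. The 678.8 may thus be too high a reference, and counts near or below it do not show a lack of difference. The end of Trim28, the heterochromatin corepressor, read 0.535% ± 0.756 in parental and 1.27% ± 1.79 in knockout cells, that of Uhrf1 0.691% ± 0.430 and 1.56% ± 1.20, and that of Setdb1 6.64% ± 3.46 and 0.571% ± 0.808. For Dnmt3b the values were 23.3% ± 33.0 and 3.59% ± 3.24, and for Dnmt3l at its lower end 51.9% ± 33.6 and 42.1% ± 18.2. For Mettl3, Dnmt1 and Dnmt3a the ends read 48.0% to 83.9% in parental cells, and which of them is the promoter is not settled by the table used. No list was called by camera at gene ends, and adjusted over the list alone 2 imprinted genes were higher in the knockout. On simulated data the test called 0% of gene ends changed by 30 points. Only a few ends of middle level were changed there, so its reach at the low levels seen here was not measured. The 0 calls are thus no evidence of unchanged gene ends.

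Chromosome 8 set the groups apart in coverage as well. Its share of listed cytosines, relative to the median autosome, was 1.24 ± 0.0101 (SD, n = 2) in parental and 1.53 ± 0.00770 in rescue WT cells, and 0.979 ± 0.00445 in knockout and 0.969 ± 0.00365 in rescue Mut cells. The ratio of knockout to parental cells was 0.788 on chromosome 8 and 0.977 to 1.16 on the other 18 autosomes. These are shares of cytosines with at least 5 calls and not copy ratios, and their size depends on the depth of a library. The methylation level of chromosome 8 lay 12.4 points below parental cells in the knockout, near the median of 11.96 points over the other 18.

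**Figure D4:**
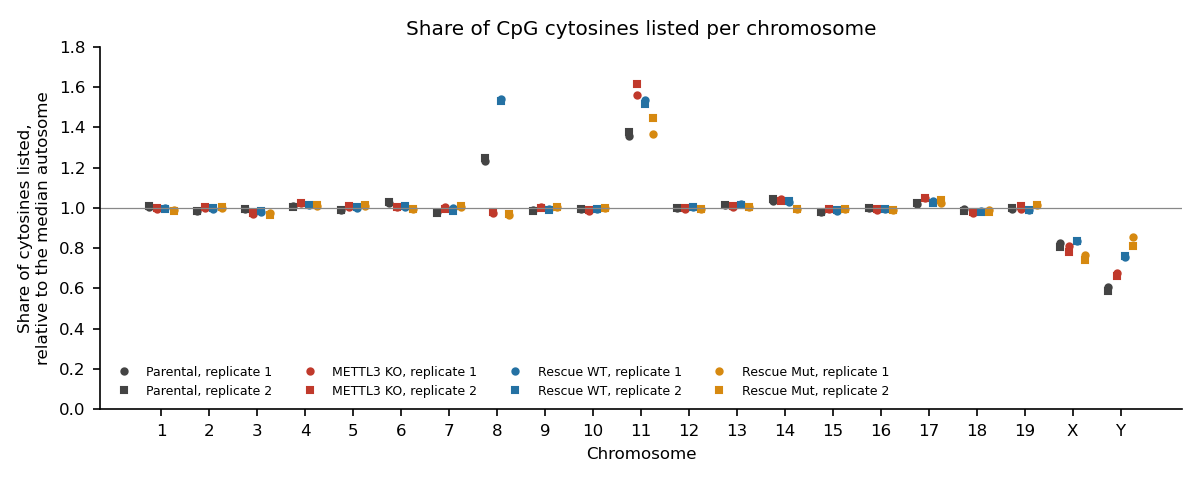
Share of CpG cytosines listed per chromosome (horizontal axis), relative to the median autosome (vertical axis), for each of 8 libraries. Chromosome 8 lies at 1.24 in parental and 1.53 in rescue WT cells and below 1 in knockout and rescue Mut cells.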

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

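The tests in this part were chosen after the results they concern had been seen, except that a limit of 50 calls per cytosine had been set before as a setting of the genome level. The share of chromosome 8 in rescue WT cells stood out because it lay above the parental libraries in data that no comparison used, at 1.53 ± 0.00770 (SD, n = 2) against 1.24 ± 0.0101. The number of gene spans that differ between the rescue lines, 9765 by edgeR, stood out because the lines lay on opposite sides of the knockout level, and the difference itself was tested. Calls over the Mettl3 gene stood out at a mean of 4.63 times the autosomal mean in rescue WT and 2.36 times in rescue Mut cells, above both parental libraries. The mitochondrial level of knockout replicate 2 stood out at 2.53%, against 0.619% in the higher of the parental libraries.

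The first pattern is the lower methylation of knockout cells. Different CpGs read in each group do not account for it, since the difference was -11.8 points at CpGs read in both, against -12.3 points at all cytosines of at most 50 calls. Loss of methylated calls in conversion would leave an equal share of the parental level everywhere, but knockout cells kept 92.0% of it in methylated windows of 30 or more CpGs and 78.9% in those of fewer than 10, with ranges between the knockout libraries of 91.6% to 92.3% and 78.4% to 79.4%. A biological difference may thus underlie the pattern, with most of it in CpG-poor sequence. Whether METTL3 loss or a separate history of the knockout cells is the source was not tested.

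The second pattern is the coverage of chromosome 8. A coverage bias shared by all chromosomes is argued against by the ratio of knockout to parental cells, 0.788 on chromosome 8 against no less than 0.977 on the other 18 autosomes. Unmodified parental cells in place of the rescue WT cells are argued against by the Mettl3 gene. There the lowest rescue WT library lay at 4.42 times its autosomal mean and the highest parental library at 1.16. Parental cells with added Mettl3 sequence would read the same, so the test cannot exclude them. Chromosome 8 as the source of the methylation difference is argued against by a median of -12.0 points over the other 18 autosomes, all lower in the knockout. A gain of chromosome 8 carried by a share of parental cells, and by more of the rescue WT cells, may fit the coverage. By their labels these are also the groups whose METTL3 is neither only knocked out nor mutant. An effect of such a gain on the rest of the genome thus stays open.

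The third pattern is that rescue Mut cells lay below the knockout and not level with it. The greater depth of the rescue Mut libraries is argued against by thinning to the shallowest library, after which the difference was -4.16 points against -4.01 points before. Cytosines above 50 calls enlarge the pattern, since the difference was -7.43 points with them, but it stood at -4.01 points without them. A further loss over time may fit if the mutant lacks activity, which was not measured, as may a difference between the lines. Neither was tested, and the labels do not say how many lines of each kind were used.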

How the results depend on the processing

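Gene spans, their lists and recovery over them, shared cytosines, the mitochondrial correction, the A filter, the thinned genome level and the other or clear gene end were chosen after seeing the data. IAP elements and the IAP level, under any setting, were not run. Over gene ends each of 76 alternative counts by edgeR or limma was 0, like the 4 counts reported, and no list at gene ends passed in 320 alternatives. In simulated data with the calls and spread of these libraries, edgeR called 41% of tiles and 0% of gene ends that were changed by 30 points. Those were few regions of middle level, so the power in the data themselves, where most of the genome differs, was not measured. Whether depth or spread between libraries sets the simulated shares was not tested.

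The genome-wide differences kept their direction under every alternative run. With cytosines above 50 calls left out, knockout minus parental was -12.3 points, rescue WT minus knockout 13.1, rescue Mut minus knockout -3.93 and rescue WT minus rescue Mut 17.1. As a mean over cytosines these were -12.3, 13.1, -3.94 and 17.1, as a median over autosomes -12.4, 13.2, -3.70 and 16.9, and at cytosines listed in all 8 libraries -9.87, 11.5, -4.20 and 15.7. Corrected for the mitochondrial level they were -9.47, 10.2, -7.12 and 17.3, without cytosines with an opposite A -12.1, 12.9, -3.94 and 16.9, and thinned -12.3, 13.1, -4.16 and 17.3. Cytosines above 50 calls, which settings that leave them out or count each cytosine once weigh less, were 70.0% methylated in the knockout against 47.1% elsewhere. Rescue WT minus parental was 1.64 points at cytosines listed in all libraries, and rescue Mut minus parental was -16.1 points as a median over autosomes, -14.1 at cytosines listed in all libraries, -16.6 with the mitochondrial correction and -16.0 without an opposite A.

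Tile counts moved most, and the cause was not tested except where fewer tiles or libraries were used. Knockout against parental gave 3824 tiles with at least 10 calls, 1820 with at least 100 calls, 3289 by limma, 0 by limma at a common median, 3153 with the replicate block and 21701 tiles of 100 kb, and 6 to 6369 with a library left out. Rescue WT against the knockout gave 8228 with at least 100 calls, 1 at a common median and 10 to 25860 with a library left out. Rescue Mut against the knockout gave 0 by limma, 0 at a common median, 7 without cytosines above 50 calls, 22 of 100 kb and 3 with at least 10 points. Rescue WT against rescue Mut gave 33162 with at least 100 calls, 31679 by limma, 1 at a common median, 24896 of 100 kb and 14 to 77290 with a library left out. The replicate numbers do not pair the libraries, since deviations of like-numbered libraries correlated at -0.0115 to 0.0223 over spans and tiles.

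Gene span counts stayed within 1.5 times in 50 of 64 alternatives. At a common median limma called 0 in each of the 4 contrasts, and for rescue Mut against the knockout limma called 0 and the limit of 10 points left 2. With a library left out the counts were 3279 to 5597, 3992 to 6621, 2 to 28 and 5129 to 10260, in the order knockout against parental, rescue WT and rescue Mut against the knockout, and rescue WT against rescue Mut. The lone library of a group was assumed to vary like the other groups.

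Recovery over gene spans was 59.5% to 84.4% in rescue WT and 0.0% to 0.224% in rescue Mut cells with a library left out, and 0.0% in rescue Mut cells with at least 10 points. Over tiles it was 0.141% to 100.0% and 0.0% to 28.6%, the extremes from runs with few called tiles. Pluripotency genes and lineage regulators lost their calls over spans with an estimated correlation, at adjusted p = 0.0625 for each of 3 contrasts, which were the only list calls over spans. In 313 alternatives a call, or mostly the lack of one, stayed as it was. Germline genes in rescue WT against the knockout passed without knockout replicate 1, and their adjusted p ranged from 0.0482 to 0.590 with a library left out.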

Other observations

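Gene families looked at after the lists, 9 in all, differed from the genome in some cases. Over 33 Hox genes the mean level was 15.3% in knockout and 13.9% in parental cells, with a median difference of 0.0737 points against -11.0 points over all gene spans. By edgeR 2 Hox genes rose and 1 fell. The 23 cadherins were all lower in the knockout, 15 of them called, and all 23 were higher in rescue WT cells, 19 of them called. The 110 vomeronasal receptor genes had a median difference of -14.9 points in the knockout, with 14 called lower. Rescue Mut minus knockout had a median of 0.148 points over their spans and -0.702 points at shared CpGs, against -4.59 points over all spans. None of the differences between a family and the other genes was tested.

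The clustered protocadherins, adhesion molecules of neurons encoded in tandem on chromosome 18, went both ways in the knockout. Of 53 genes 10 rose and 10 fell, with a median difference of -4.12 points over spans and 2.895 points at shared CpGs, and the spans of a cluster overlap each other. In rescue Mut cells 9 of the 53 fell relative to the knockout and 0 rose by edgeR, with a median of -7.27 points, while limma called 0 of all spans in that contrast and edgeR placed 75 of all spans higher at an unadjusted p under 0.05. In rescue WT cells 34 stood above rescue Mut cells.

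Calls at cytosines of more than 50 calls lay mostly in a few intervals. The first 100 kb listed on chromosome 9, from 3000001 to 3100000, held 50.6% of them and read 74.8% ± 0.136 (SD, n = 2) in parental, 72.5% ± 0.144 in knockout, 75.8% ± 0.0813 in rescue WT and 66.5% ± 0.0880 in rescue Mut cells. Chromosome 2 from 98600001 to 98700000 held 28.8% of them and read 74.6% ± 0.191, 71.6% ± 0.553, 75.8% ± 0.153 and 66.2% ± 0.174. Knockout and rescue Mut cells both lay nearer to parental cells in these intervals than at cytosines of at most 50 calls in every library, where parental cells read 59.4%, the knockout 47.1% and rescue Mut cells 43.1%. What sequence they hold is not given by the gene table.

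In 1 kb windows methylated at 80% or more in parental replicate 1, read against parental replicate 2, rescue WT cells kept 103% of the level in windows of fewer than 10 CpGs and rescue Mut cells 72.9%, and in windows of 30 or more CpGs 101% and 83.7%. Chromosome 11 was listed at 1.37 ± 0.0144 (SD, n = 2) times the median autosome in parental and 1.59 ± 0.0384 in knockout cells. The values were 1.53 ± 0.0140 in rescue WT and 1.41 ± 0.0552 in rescue Mut cells. Of its cytosines 64.1% and 56.3% were listed in the rescue Mut libraries, against 23.3% and 25.1% in the knockout. The ratios depend on depth and are not copy ratios, so their sizes do not rank the deeper rescue Mut libraries among the groups. At like depth the knockout lay above parental cells. Parental replicate 2, with 4727183 cytosines listed, read 1.38. Knockout replicates 1 and 2, with 4639234 and 4845758, read 1.56 and 1.62. The cause was not tested. On the Y chromosome rescue Mut cells read 43.4% and the knockout 40.4%, the reverse of their order on all 19 autosomes. Outside Mettl3, the 5 windows with excess calls in both rescue lines lay in Jmjd1c, in Specc1 and in 3 intervals without a gene.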
